A study of Mus musculus with 43 samples.

How the data were processed

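RNA was sequenced from germ cell cultures of wild-type (WT) and Stra8-knockout (KO) mice. Per the labels' protocols, the cultures were started from THY1-positive testis cells and kept in serum-free medium with 20 ng/ml GDNF, 150 ng/ml GFRA1 and 1 ng/ml FGF2 on STO feeder cells, a mouse fibroblast line, between passages 3 and 12. Cultures received all-trans retinoic acid (RA) or the solvent DMSO at 0.01% for 4, 8 or 24 h, and untreated cultures were taken at 0 h. The labels state the RA dose as 0.01 M, which no value in the files can check. Whether this is the concentration in the culture or that of a stock stays open. RNA of all samples was isolated on the same day, samples with an RNA integrity number of at least 9.2 were used, and libraries were made with a stranded mRNA kit, per the labels' protocols.

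The labels name 6 replicates, WT17, WT23 and WT25 for WT and KO12, KO20 and KO21 for KO. They are called culture lines here because each name recurs in every condition, although the labels do not use that word. Each gave 1 library in each of the 7 conditions of its genotype. The labels list 43 samples because line WT17 at 24 h of RA has 2, whereas a single column holds it in the deposited table, so 42 libraries in 14 groups of 3 were analysed. P-values rest on the spread between culture lines within groups, pooled over all 14 groups of 3 and not taken from the compared groups alone. The main fit treats the libraries of a line as independent. The labels do not say whether each came from a separate mouse.

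The submitters' processing notes name STAR 2.5.1b, DESeq and the genome build GRCm38.p4, with no role or order. The read counter and its strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes remain uncertain. The deposited table holds 46983 genes with values on a log2 scale that the authors had scaled between libraries, per the file headers and the values themselves, which range from -4.5 to 18. Genes with few reads lie close to their own mean in every library, as in a regularized log transform, so changes of low genes are understated. The authors' mean signal per gene, a mean of scaled counts over all libraries, was used for description. Deposited comparison columns hold the authors' log2 fold changes and adjusted p-values and were used only where the authors' deposited table is named. Total read counts per library are not kept in these values, so depth is unknown and no counting interval is given. Gene coordinates are those of the deposited table.

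The test planned for raw counts did not apply, and the form planned for log values was used. Genes with a value of at least log2 of 10 in at least 3 libraries were kept, which left 16297 genes. A linear model with 1 mean per group was fitted over all 14 groups with limma 3.58.1 in R 4.3.3 (data.table in version 1.17.8), with moderated variances (trend and robust options). P-values were adjusted by the Benjamini-Hochberg method (BH) over the genes tested, with a threshold of 0.05 in each comparison. RA was compared with DMSO at each time in each genotype. The interaction is the RA effect in KO minus the RA effect in WT, so a positive value means a higher response in KO. Further contrasts compared the RA effect at 24 h with that at 4 h, KO with WT untreated and at 24 h of RA, and DMSO at 24 h with untreated cultures, 15 comparisons in all. Errors of log2 changes are standard errors (SE) of the model with n = 3 lines per group, and errors of group means are standard deviations (SD).

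The groups, comparisons, filter, test, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest changes in each direction among genes past the threshold (5 for the KO comparisons, the contrasts between times, KO against WT at 24 h of RA and the DMSO comparisons). All 3 lines had to move the same way, or the genotypes had to show no overlap. The mean in the higher group had to be above 5 times the filter level, and predicted models, unnamed clones and pseudogenes were left out. Stra8, Tcerg1l, Kit, Gfra1, Zbtb16, Rarb, Cyp26a1, Cyp26b1 and Dhrs3 were always named, with up to 4 members with the largest changes of each list among those past the threshold, or up to 2 with the highest levels where no member passed. Some genes that meet the rule are not reported here, and counts include them.

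The 22 gene lists hold 538 different genes, of which 463 were tested. They cover RA signalling and metabolism, Hox genes, undifferentiated spermatogonia, differentiating spermatogonia, meiotic prophase, the piRNA pathway and germ cell RNA granules, GDNF and FGF signalling targets, immediate early genes, G1/S and G2/M phases of the cell cycle, p53 targets and apoptosis, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, and DNA methylation and chromatin regulators. Markers of other cells cover feeder fibroblasts, Sertoli cells, Leydig cells, macrophages, endothelium and spermatids. Lists share members. Lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted by BH over the lists of a comparison. The test was repeated with a correlation estimated from the data.

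The names pair the libraries, since each recurs in every group of its genotype and is taken as 1 culture line. Deviations from the group means correlated over genes within a line at a mean r of 0.22 to 0.53, with single pairs of a line down to -0.17. With other lines the mean r was -0.32 to -0.15. Taking deviations from the group mean itself pushes the values with other lines below 0. It does not push the values within a line above 0, since those pairs come from different groups. Libraries of a line were thus alike on average, which the main fit leaves out. The fit with the line as a block was an alternative. Further settings fixed in advance were quantile normalization, no filter, a 2-fold limit (an absolute log2 change of 1), only the groups compared, limma without trend and robust options, and each line left out in turn. Fits without 2 or 3 of the DMSO libraries at 4 h were added after the data were seen.

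The fit was tested on simulated values for WT RA against DMSO at 24 h over 16297 genes, with 200 genes changed. The simulated noise was independent between libraries with the same SD in every library for a gene, without effects of culture line or outlying libraries. At 3 lines per group, 61.3% of the genes changed by a log2 of 0.5 were recovered, 95% at 1 and 100% at 2, with 7 false calls. These figures hold for that setting only. Transcript length and GC share came from the longest GENCODE M21 transcript of each gene. Plots were drawn with matplotlib 3.10.9.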

Results

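Transcript levels were compared in mouse spermatogonial cultures with and without the Stra8 gene, at 4, 8 and 24 h of RA or DMSO and untreated at 0 h, with 3 culture lines in each of 14 groups. The study's title names the roles of Stra8 and Tcerg1l in the differentiation of spermatogonia under RA, the vitamin A derivative that starts differentiation and meiosis in the testis. The authors' column names remark on 2 DMSO libraries at 4 h, those labelled WT25 and KO20, the first as an outlier and the second as tracking with KO at 24 h of RA. A library labelled WT23 DMSO 4 h also stood apart, with Stra8 at log2 11.59 against 7.93 in WT17 and 8.12 in WT25. Since the spread is shared over all groups, these 3 libraries widen the errors at every time. Counts without them are given beside the counts over all 42 libraries, except for comparisons that use WT DMSO at 4 h. Leaving the 3 out keeps WT17 as the only library of that group, so those comparisons are given without p-values or counts.

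Stra8, a gatekeeper of meiotic entry induced by RA (chromosome 6, 34920163 to 34939344, build GRCm38.p4), was lower in KO than in WT in every condition, and its transcript was still measured in KO. In untreated cultures its level was log2 8.06 ± 0.73 in WT and 6.39 ± 0.09 in KO (SD, n = 3), a difference of 3.19-fold that did not pass the limma test (adjusted p = 1, but 0.00069 without the 3 libraries in doubt). At 24 h of RA it was 14.50 ± 0.35 in WT and 9.65 ± 0.16 in KO, 28.9-fold higher in WT (adjusted p = 3.2e-07). RA raised the KO transcript too, by a log2 of 2.32 ± 0.60 (SE) at 8 h and 3.08 ± 0.60 at 24 h. In the library labelled KO20 DMSO 4 h the Stra8 value was 9.64, against 6.46 and 6.63 in KO12 and KO21 at the same condition and 9.47 to 9.79 in KO at 24 h of RA. Over 7915 genes its log2 values differed from those of KO20 at 24 h of RA with an SD of 0.0403, against 0.102 for the lowest of 860 other pairs of libraries.

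**Figure D1:**
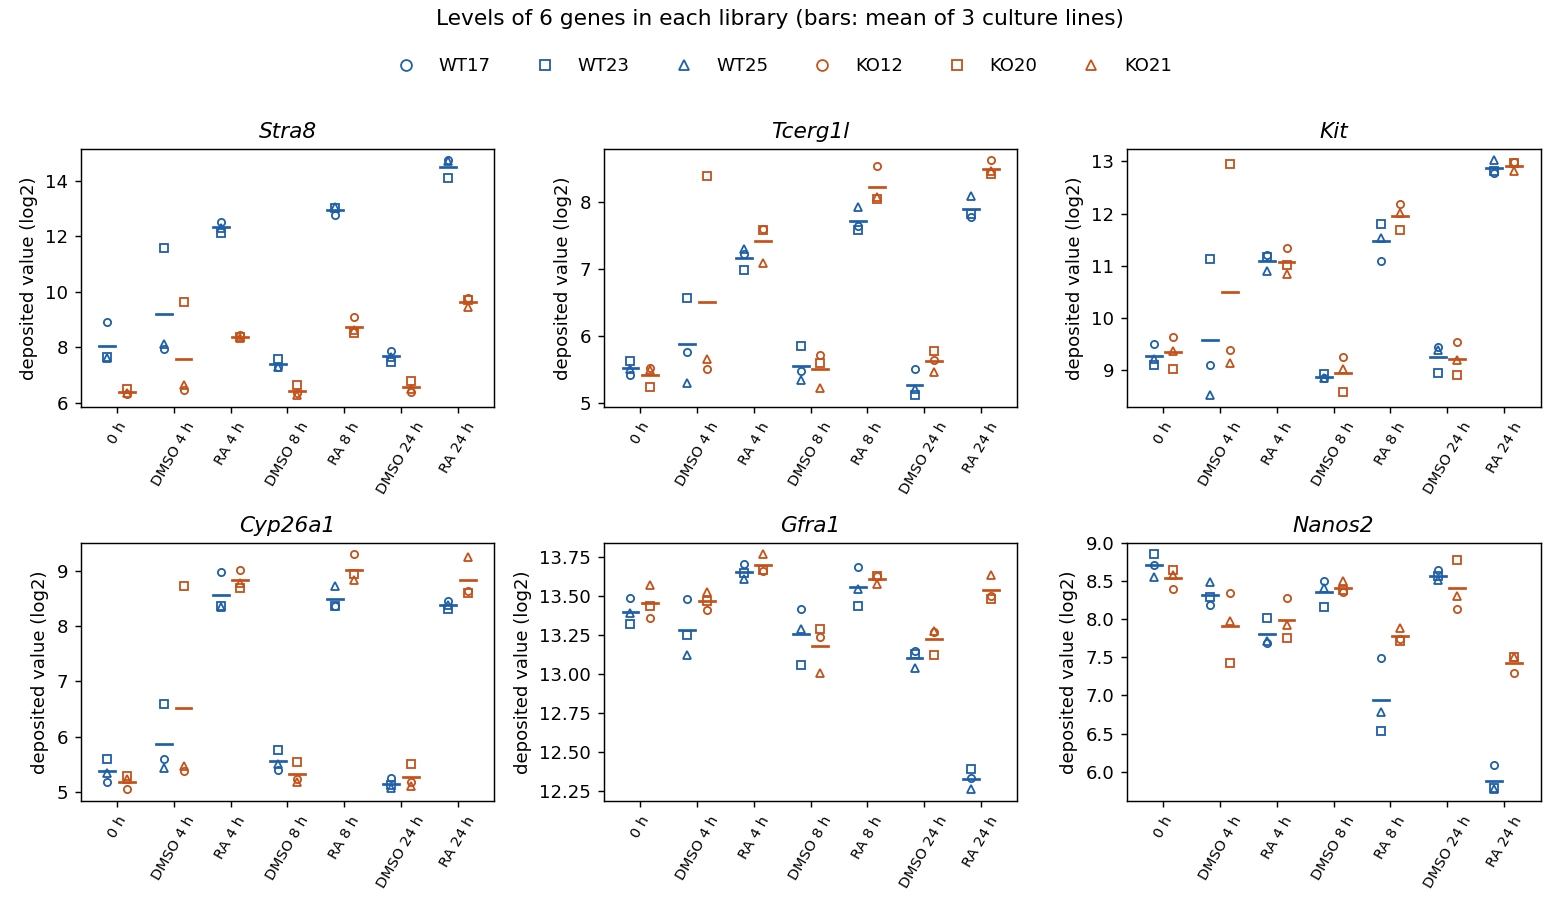
Deposited log2 values of 6 genes in each library, by condition on the x axis, with 1 symbol per culture line and bars at the mean of 3 lines, WT in blue and KO in orange. Kit reached 12.87 in WT and 12.92 in KO at 24 h of RA, Gfra1 was at 12.32 in WT and 13.54 in KO, and the KO20 DMSO 4 h library lies at 12.96 for Kit.

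In WT cultures after 4 h of RA, the RA-degrading enzyme Cyp26a1 rose by a log2 of 2.70 ± 0.44 (SE, n = 3 lines, 6.52-fold, adjusted p = 3e-04) and Stra8 by 3.10 ± 0.60 (8.59-fold, adjusted p = 0.0023). The change of Stra8 was 4.39 without the 3 libraries in doubt, with WT17 as the only DMSO control. Ccdc88b rose by 2.53 ± 0.55, Rgl3 by 2.43 ± 0.47, Agpat3 by 1.86 ± 0.35 and Npr1, a natriuretic peptide receptor, by 1.68 ± 0.26. The pluripotency factor Sall4 rose by 0.90 ± 0.12 and Spred2, an inhibitor of ERK signalling, by 0.95 ± 0.09. Cish, a STAT5-induced inhibitor of cytokine signalling, fell by 0.63 ± 0.10 and Ube2ql1 by 0.82 ± 0.17. Tcerg1l, Rarb and Kit had log2 changes of 1.29 ± 0.38, 1.38 ± 0.42 and 1.51 ± 0.55 and did not pass over all libraries (adjusted p = 0.056, 0.058 and 0.1). Without the 3 libraries in doubt their changes were 1.41, 1.61 and 1.98, again against WT17 alone. With the line as a block Tcerg1l and Rarb passed (adjusted p = 0.033 and 0.034).

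limma called 489 of 16297 genes in WT at 4 h, 381 higher and 108 lower. The count was 1458 with the line as a block. None is given without the 3 libraries, since WT17 is then the only DMSO control. Leaving out the library labelled WT25 alone gave 184, KO20 alone 829 and WT23 alone 4297. Of 28 measured RA signalling genes 2 rose, Cyp26a1 and the nuclear receptor corepressor Nrip1 (0.77 ± 0.19, and 0.62 without the 3 libraries). Adjusted over the list alone, 5 rose and 3 fell. Oxidative phosphorylation was the 1 list past the camera test, with a median log2 change of -0.23. Of its 31 members 1 was lower (Cox6a1, at -0.11 without the 3 libraries), and 12 were lower adjusted over the list alone. The adjusted p of the list was 1.8e-06, 0.93 with an estimated correlation and 0.31 without the libraries labelled WT25 and KO20. Gfra1, the GDNF co-receptor, rose by 0.37 ± 0.09 over all libraries (adjusted p = 0.0098), with a change of 0.17 without the 3 libraries.

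After 8 h, Stra8 was up by a log2 of 5.54 ± 0.60 in WT (46.4-fold, adjusted p = 3.2e-07), Kit, the stem cell factor receptor of differentiating spermatogonia, by 2.60 ± 0.55 (6.04-fold). The RA receptor Rarb rose by 2.51 ± 0.42 (5.68-fold). Cyp26a1 rose by 2.94 ± 0.44, Tcerg1l by 2.16 ± 0.38 (4.47-fold), Fndc5 by 2.34 ± 0.32, Tinagl1 by 2.08 ± 0.22 and the meiotic cohesin Rec8 by 1.84 ± 0.31. Nanos2, an RNA-binding protein that keeps male germ cells undifferentiated, fell by 1.42 ± 0.19. Other falls were in Abhd12b by 1.57 ± 0.18, Lgr5 by 1.26 ± 0.20, the ubiquitin ligase Fbxo32 by 1.25 ± 0.14 and Cachd1 by 1.19 ± 0.13.

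In all, 834 genes passed in WT at 8 h, 318 higher and 516 lower, with 1958 without the 3 libraries and 1501 with the line as a block. Of 36 genes of undifferentiated spermatogonia 7 fell and 2 rose, with Id4 down by 0.84 ± 0.25, Nanos3 by 0.77 ± 0.16 and Tcl1 by 0.76 ± 0.15 (adjusted over the list alone, 9 fell and 2 rose). Of 27 GDNF and FGF targets 6 fell and 1 rose, among the falls the transcription factors Egr2 by 0.92 ± 0.21, Egr4 by 0.89 ± 0.18 and Mycn by 0.69 ± 0.13 (adjusted over the list alone, 9 fell and 1 rose). G1/S genes went the other way, with 3 of 33 higher (9 higher and 1 lower adjusted over the list alone), Cdc6 by 0.36 ± 0.06 and Cdc45 by 0.22 ± 0.06. Cholesterol synthesis had 2 of 22 members lower over all genes and over the list alone, among them Sqle by 0.28 ± 0.07. The camera adjusted p was 0.0028 for undifferentiated spermatogonia, 8.2e-05 for GDNF and FGF targets, 1.7e-06 for G1/S and 2.4e-05 for cholesterol synthesis. The values were adjusted p = 0.38, 0.47, 0.38 and 0.51 with an estimated correlation.

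By 24 h of RA, Stra8 had risen by a log2 of 6.83 ± 0.60 in WT (114-fold, n = 3 lines, adjusted p = 3.9e-10) and Kit by 3.62 ± 0.55 (12.3-fold, adjusted p = 9e-06). The RA response genes Cyp26a1 (3.25 ± 0.44), Rarb (2.91 ± 0.42), Cyp26b1 (2.55 ± 0.35) and Tgm2 (2.22 ± 0.39) rose. So did Ccdc88b (3.26 ± 0.55), the transcription factor Foxn4 (2.93 ± 0.35), Tcerg1l (2.63 ± 0.38, chromosome 7, 138208974 to 138397730), Fndc5 (2.41 ± 0.32) and the signalling protein Wnt7b (2.40 ± 0.40). Nanos2 fell by 2.69 ± 0.19 and the oestrogen receptor Esr2 by 2.21 ± 0.17. Ighm fell by 2.25 ± 0.22, Cd7 by 2.14 ± 0.22, the neurofilament gene Nefm by 1.99 ± 0.19 and Sall3 by 1.94 ± 0.22. Zbtb16, a transcription factor of spermatogonial stem cells, fell by 1.17 ± 0.14 (adjusted p = 2.3e-07). Gfra1, up at 8 h by 0.30 ± 0.09, was down by 0.79 ± 0.09 at 24 h (log2 -0.79, adjusted p = 2e-08). limma called 3949 genes, 1926 higher and 2023 lower, and 6054 without the 3 libraries.

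Of the 36 undifferentiated spermatogonia genes, 20 fell and 1 rose in WT at 24 h (21 and 2 adjusted over the list alone), with Tspan8 down by 1.76 ± 0.22, Tcl1 by 1.71 ± 0.15 and Nanos3 by 1.43 ± 0.16. The median log2 change was -0.59 (adjusted p = 1.5e-12, and adjusted p = 0.0019 with an estimated correlation). Of the 27 GDNF and FGF targets 20 fell and none rose (21 fell adjusted over the list alone), with Egr2 down by 1.90 ± 0.21 and the ERK phosphatase Dusp6 by 1.55 ± 0.17. The list's adjusted p was 1.2e-14, and adjusted p = 0.055 with an estimated correlation. Of 25 immediate early genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), among them Ier3 by 1.33 ± 0.28 and Egr1 by 1.26 ± 0.18 (adjusted p = 0.0021, and adjusted p = 0.33 with an estimated correlation).

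Differentiating spermatogonia genes rose in 10 of 23 cases and fell in 2 (10 and 3 adjusted over the list alone), the falls including the transcription factor Dmrtb1 by 1.19 ± 0.15. Of 39 meiotic prophase genes 13 rose and 1 fell (16 and 2 adjusted over the list alone), with Rec8 up by 1.97 ± 0.31, Gm4969 (now named Meiosin) by 1.19 ± 0.19, the recombination-site methyltransferase Prdm9 by 0.74 ± 0.13 and Sycp3 of the synaptonemal complex by 0.56 ± 0.15. The adjusted p was 0.0072 and 0.0059 for these lists, and adjusted p = 0.33 for both with an estimated correlation. RA signalling had 8 of 28 members higher and 4 lower, the same counts adjusted over the list alone, at an adjusted p of 0.031 (adjusted p = 0.33 with an estimated correlation).

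Cholesterol synthesis, glycolysis, G1/S and mitochondrially encoded genes lay lower in WT at 24 h. Cholesterol synthesis had 9 of 22 members lower and none higher, with the pathway's regulator Srebf2 down by 0.48 ± 0.10 (9 adjusted over the list alone). Glycolysis had 6 of 22 lower (8 adjusted over the list alone), with Pkm down by 0.60 ± 0.11 and Hk2 by 0.57 ± 0.11. G1/S genes fell in 10 of 33 cases and rose in 1, also adjusted over the list alone, among them the cyclins Ccnd2 by 0.70 ± 0.10 and Ccnd1 by 0.53 ± 0.11. Mitochondrially encoded genes fell in 4 of 7 cases, also adjusted over the list alone, with mt-Nd1 down by 0.24 ± 0.07 and mt-Cytb by 0.18 ± 0.05. Under quantile normalization all 4 lost the call, with log2 changes of 0 for mt-Nd1 and mt-Cytb, -0.10 for mt-Nd2 and -0.01 for mt-Nd4 (adjusted p = 1, 1, 0.52 and 0.95). The adjusted p was 7e-04 for cholesterol synthesis, 0.00046 for glycolysis, 0.0017 for G1/S and 0.049 for mitochondrially encoded genes (0.076 with the line as a block). The values were adjusted p = 0.43, 0.4, 0.34 and 0.33 with an estimated correlation.

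The other lists did not pass in WT at 24 h. Of 30 p53 and apoptosis genes 5 rose and 9 fell, also adjusted over the list alone, with Perp up by 1.75 ± 0.19 and Bbc3 down by 0.86 ± 0.20 (adjusted p = 0.15). Of 25 DNA methylation and chromatin regulators 7 fell and 1 rose (8 and 1 adjusted over the list alone), with Tet1 down by 1.18 ± 0.36 and Dnmt3b up by 0.69 ± 0.12 (adjusted p = 0.15). Of 24 piRNA pathway genes 4 fell and 2 rose, also adjusted over the list alone, Tdrd5 falling by 0.76 ± 0.09 (adjusted p = 0.19). Hox genes had 2 of 19 higher, Hoxb13 and Hoxa4 (adjusted p = 0.38, none adjusted over the list alone). G2/M had 1 of 30 higher, Nuf2 by 0.25 ± 0.08 (adjusted p = 0.15, none adjusted over the list alone), and oxidative phosphorylation 3 of 31 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.98).

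Markers of other cell types were measured beside these lists. Feeder fibroblast genes were abundant, with a median log2 level of 9.83 over 28 genes and Fn1 at 14.08. Of these, 1 changed in WT at 24 h, Col1a1, which fell by 0.63 ± 0.13 (adjusted p = 0.79 for the list). Of 14 Sertoli genes 2 rose and 2 fell, with Clu up by 0.74 ± 0.21 (adjusted p = 0.85). Of 5 macrophage genes 2 fell, Mrc1 by 1.85 ± 0.26 and Ptprc by 1.16 ± 0.23 (adjusted p = 0.058). Of 7 endothelial genes 2 fell, Tek by 0.73 ± 0.23 and Pecam1 by 0.67 ± 0.24 (adjusted p = 0.15). No spermatid gene passed among 9 (adjusted p = 0.85). Of 4 Leydig genes, too few for a list test, Fdx1 and Star had changes of 0.17 ± 0.17 and 0.03 ± 0.25. These counts were the same adjusted over the list alone for the 5 lists tested. Median levels were 5.05 for Sertoli, 5.24 for Leydig, 5.96 for macrophage, 6.61 for endothelial and 6.96 for spermatid genes, against 10.96 for undifferentiated spermatogonia.

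**Figure D2:**
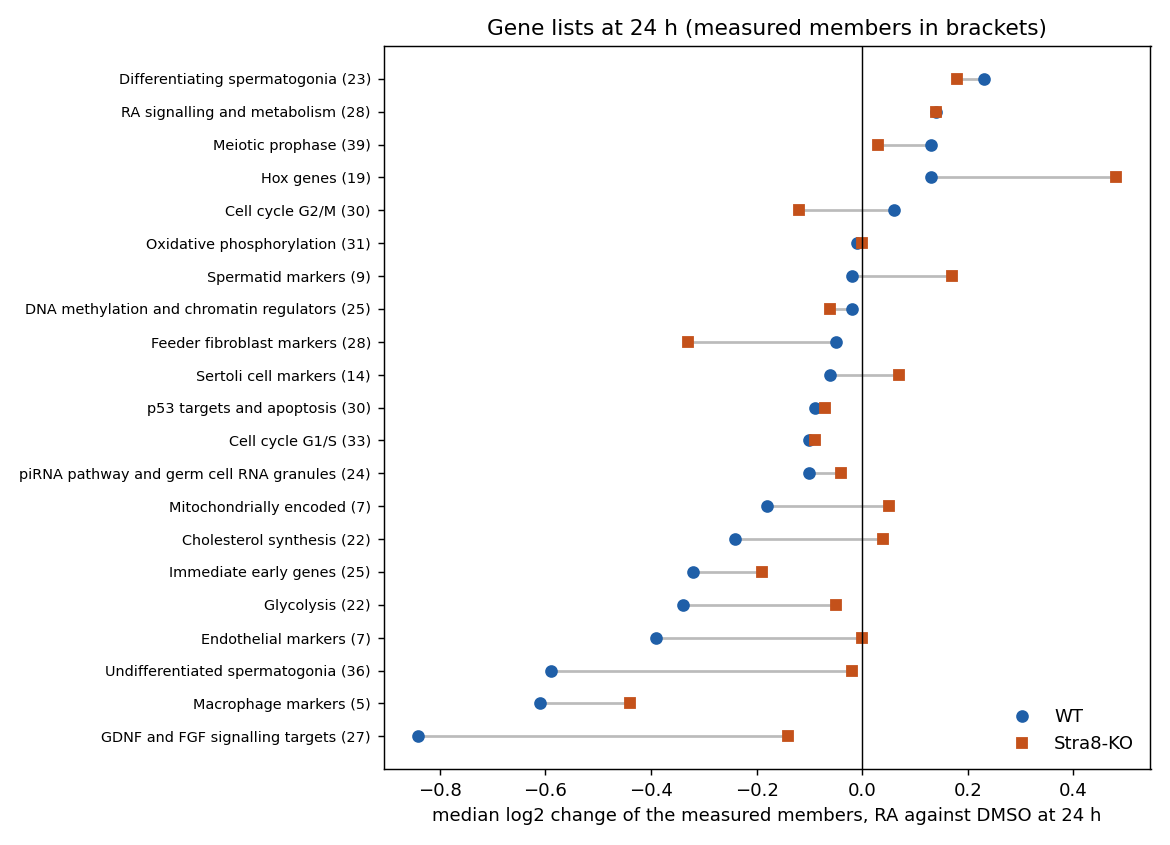
Median log2 change, RA against DMSO at 24 h, of the measured members of 21 gene lists, with circles for WT and squares for KO. Undifferentiated spermatogonia genes lie at -0.59 in WT and -0.02 in KO, and GDNF and FGF targets at -0.84 and -0.14.

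In KO cultures, Cyp26a1 rose by a log2 of 2.31 ± 0.44 at 4 h (4.97-fold, n = 3 lines, adjusted p = 0.0049), Fndc5 by 1.42 ± 0.32, Col6a5 by 1.19 ± 0.26, Hpca by 1.14 ± 0.20, Spred2 by 0.60 ± 0.09 and Sall4 by 0.61 ± 0.12. Cish fell by 0.51 ± 0.10. The change of Cyp26a1 was 3.42 and that of Fndc5 2.11 without the 3 libraries (adjusted p = 2.1e-14 and 6.6e-08). limma called 75 genes, 74 higher and 1 lower. The count was 448 without the 3 libraries, 322 without the library labelled KO20 alone, 142 without WT25 alone and 186 with the line as a block. Without the 3 libraries Rarb (1.87), Tcerg1l (1.85), Stra8 (1.84) and Kit (1.80) passed in KO at 4 h (adjusted p = 1.2e-07, 8.3e-09, 1.2e-05 and 2.2e-06). GDNF and FGF targets lay higher at 4 h, at a median of 0.18 with 1 of 27 called (5 adjusted over the list alone). The list's adjusted p was 6e-07, but 0.88 without the 3 libraries and adjusted p = 0.49 with an estimated correlation. The lists past the camera test without the 3 libraries were RA signalling (8 of 28 higher), differentiating spermatogonia (5 of 23 higher) and Hox genes (3 of 19 higher). Their adjusted p was then 8.2e-08, 0.00019 and 0.0088, against 0.11, 0.71 and 0.025 over all libraries.

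At 8 h in KO, Ccdc88b rose by 4.10 ± 0.55 (17.2-fold), Cyp26a1 by 3.72 ± 0.44, Rgl3 by 3.27 ± 0.47, Kit by 3.0 ± 0.55, Rarb by 2.81 ± 0.42 and Tcerg1l by 2.71 ± 0.38. Snap25 fell by 1.13 ± 0.32. Of 28 RA signalling genes 10 rose, also adjusted over the list alone, among them the carotenoid-cleaving enzyme Bco1 by 1.69 ± 0.31 and Dhrs3, which reduces retinal, by 0.91 ± 0.16 (adjusted p = 1.7e-06, and adjusted p = 0.074 with an estimated correlation). Of 19 Hox genes 4 rose (5 adjusted over the list alone), Hoxb13 by 1.70 ± 0.46, Hoxb4 by 1.13 ± 0.21, Hoxb1 by 0.92 ± 0.19 and Hoxb5 by 0.69 ± 0.20 (adjusted p = 2.7e-07, and adjusted p = 0.18 with an estimated correlation). Under quantile normalization Hoxb5 lost the call, at 0.64 (adjusted p = 0.083). limma called 523 genes, 472 higher and 51 lower, with 1068 without the 3 libraries and 885 with the line as a block.

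At 24 h in KO, Ccdc88b was up by 4.24 ± 0.55 (18.8-fold), Kit by 3.69 ± 0.55 (12.9-fold) and Cyp26a1 by 3.57 ± 0.44. Other rises were in Rgl3 by 3.48 ± 0.47, the keratin gene Krt73 by 3.41 ± 0.44, Rarb by 3.23 ± 0.42, Tcerg1l by 2.87 ± 0.38 and Rec8 by 2.29 ± 0.31. Gfra1 rose by 0.32 ± 0.09 (adjusted p = 0.013) and Zbtb16 had a change of -0.30 ± 0.14 (adjusted p = 0.23, and 0.0021 without the 3 libraries). Of 36 undifferentiated spermatogonia genes 6 rose and 4 fell (8 and 4 adjusted over the list alone), with Utf1 up by 1.34 ± 0.26, Sall4 by 1.07 ± 0.12 and Nanos2 down by 0.97 ± 0.19 (adjusted p = 0.7 for the list). RA signalling had 11 of 28 higher and 1 lower (11 and 3 adjusted over the list alone, adjusted p = 0.00011) and Hox genes 5 of 19 higher (8 adjusted over the list alone, adjusted p = 0.0039), with adjusted p = 0.21 and 0.85 with an estimated correlation. Differentiating spermatogonia genes rose in 7 of 23 cases (8 adjusted over the list alone), and GDNF and FGF targets fell in 4 of 27 and rose in 2 (6 and 2 adjusted over the list alone). Their adjusted p was 0.0039 and 0.046, against adjusted p = 0.75 and 0.85 with an estimated correlation. G1/S genes fell in 3 of 33 cases and rose in 1 (4 and 1 adjusted over the list alone), and Mcm10 fell by 0.28 ± 0.07 while Chaf1b rose by 0.52 ± 0.17. Under quantile normalization the fall of Rrm2 (adjusted p = 0.06) and the rise of Hoxb5 at 24 h (adjusted p = 0.057) lost the call. Of 30 G2/M genes 1 fell, Nusap1 by 0.31 ± 0.10 (adjusted p = 0.059 under quantile normalization, none adjusted over the list alone), at a median of -0.12. The adjusted p of these lists was 0.0039 and 0.0052, and adjusted p = 0.85 for both with an estimated correlation.

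Feeder fibroblast genes lay lower in KO at 24 h, at a median log2 change of -0.33 with 2 of 28 called (3 adjusted over the list alone), Col6a2 by -0.82 ± 0.22 and Col1a1 by -0.54 ± 0.13, at an adjusted p of 0.0039 (adjusted p = 0.85 with an estimated correlation). The extracellular matrix genes Adamts5 and Dpt, outside the list, fell by 1.45 ± 0.35 and 1.34 ± 0.41. limma called 1440 genes in KO at 24 h, 1037 higher and 403 lower, with 3023 without the 3 libraries and 2366 with the line as a block.

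**Figure D3:**
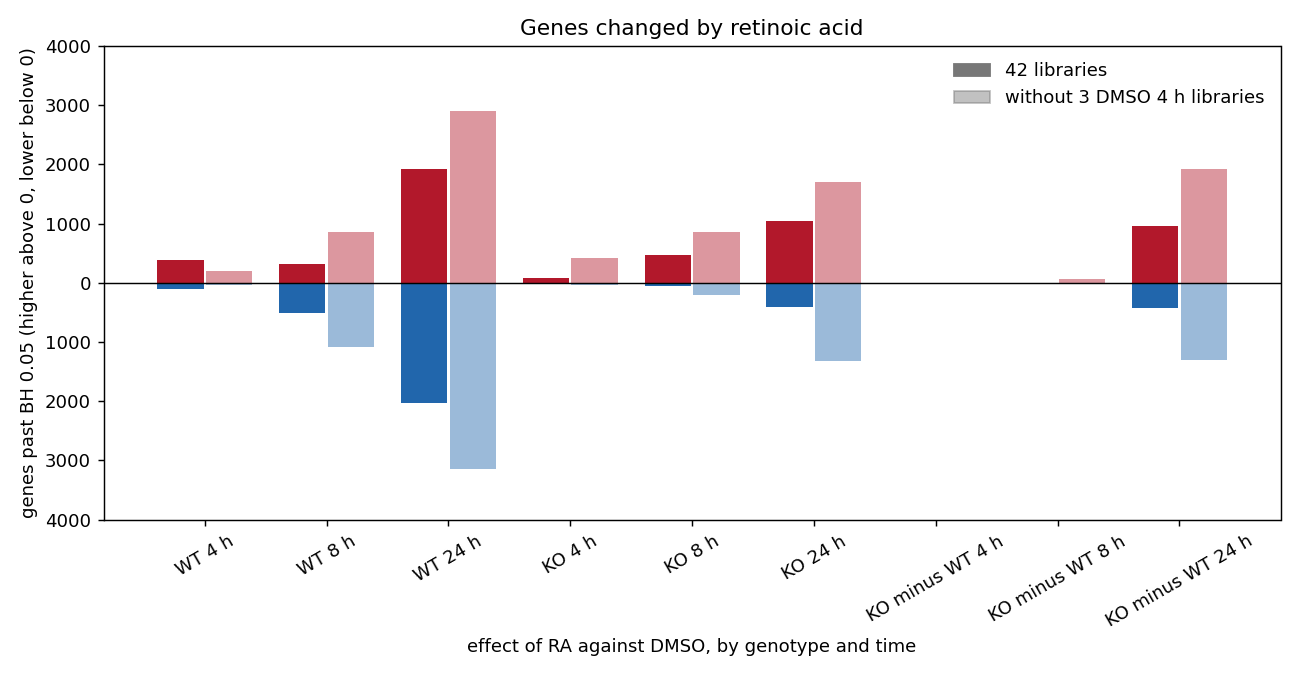
Genes past BH 0.05 for RA against DMSO in WT and KO and for the difference of the RA effects (KO minus WT), with higher genes above 0 and lower genes below 0 on the y axis and pale bars for the fit without 3 DMSO 4 h libraries. The WT count at 24 h is 3949 over all libraries and 6054 without the 3, and the KO count is 1440 and 3023. At 4 h the pale bars of WT and of KO minus WT rest on WT17 as the only WT DMSO library.

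Genes that rose in both genotypes numbered 60 at 4 h, 206 at 8 h and 346 at 24 h, against 1.73, 9.21 and 123 for independent lists. Genes that fell in both numbered 1, 41 and 227, against 0.00663, 1.61 and 50. WT and KO comparisons contrast different libraries, but both use the same spread of each gene, estimated over all groups. Genes with a small spread pass more readily in both, so the counts for independent lists can be too low. Without the 3 libraries the shared rises at 8 and 24 h were 426 and 691 and the shared falls 154 and 691. With the line as a block there were 116 shared rises and 10 shared falls at 4 h, 121 shared falls at 8 h, and 535 shared rises and 419 shared falls at 24 h.

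Whether the response to RA depended on Stra8 was tested by the interaction. At 24 h the response was higher in KO for the germ cell RNA-binding proteins Nanos3, by a log2 of 2.01 ± 0.23 (adjusted p = 4.6e-07), and Nanos2, by 1.71 ± 0.27 (adjusted p = 6.9e-05). It was also higher in KO for Gfra1 by 1.11 ± 0.12 (adjusted p = 2.4e-07) and for Zbtb16 by 0.87 ± 0.20 (adjusted p = 0.0051). Krt73 (3.19 ± 0.62), Kndc1 (3.08 ± 0.66), Dnah17 (2.64 ± 0.51), Slc5a4a (2.62 ± 0.43) and the Notch regulator Dtx1 (2.47 ± 0.40) had the highest values under the naming rule. Responses were lower in KO for Stra8 itself (-3.75 ± 0.84), the transcription factor Ikzf1 (-1.41 ± 0.27), the p53 target Perp (-1.36 ± 0.26) and Tgm1 (-1.28 ± 0.23). No difference passed for Kit (0.08 ± 0.77), Rarb (0.32 ± 0.59), Cyp26a1 (0.32 ± 0.62), Cyp26b1 (-0.28 ± 0.49) or Tcerg1l (0.24 ± 0.54). The SEs of these 5 differences were 0.27, 0.26, 0.24, 0.32 and 0.22 without the 3 libraries, with the same values and no call. Dhrs3 had a higher response in KO (0.83 ± 0.22, adjusted p = 0.014).

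Of 36 undifferentiated spermatogonia genes, 20 had a higher response in KO at 24 h and none a lower one (24 adjusted over the list alone), at a median difference of 0.81 (adjusted p = 4.5e-15, and adjusted p = 0.00048 with an estimated correlation). Of 27 GDNF and FGF targets 10 were higher (15 adjusted over the list alone), with Egr4 at 1.72 ± 0.25, Nefm at 1.46 ± 0.26 and Mycn at 1.38 ± 0.18 (adjusted p = 5.3e-11, and adjusted p = 0.16 with an estimated correlation). Cholesterol synthesis had 4 of 22 members higher (10 adjusted over the list alone), among them Dhcr7 by 0.58 ± 0.16 (adjusted p = 0.00011, and adjusted p = 0.66 with an estimated correlation). Of 39 meiotic prophase genes 3 had a lower response in KO (5 adjusted over the list alone), Ugt8a, an enzyme of galactolipid synthesis, by -0.49 ± 0.13, the recombinase Dmc1 by -0.38 ± 0.10 and the cohesin Smc1b by -0.38 ± 0.12 (adjusted p = 0.041, 0.058 with the line as a block, and adjusted p = 0.51 with an estimated correlation). G2/M genes lay lower in KO, at a median difference of -0.18 with 1 of 30 called, also adjusted over the list alone, Nusap1 by -0.52 ± 0.14 (adjusted p = 0.00061, and adjusted p = 0.75 with an estimated correlation). For G1/S the response was higher in KO in 2 of 33 cases and lower in 1 (4 and 1 adjusted over the list alone, adjusted p = 0.45). Glycolysis had 1 of 22 higher, Pkm, also adjusted over the list alone (adjusted p = 0.01, and adjusted p = 0.75 with an estimated correlation). Mitochondrially encoded genes had 1 of 7 higher, mt-Nd2 (4 adjusted over the list alone), at an adjusted p of 0.036 (0.059 with the line as a block, and adjusted p = 0.44 with an estimated correlation). Under quantile normalization mt-Nd2 had a difference of 0.05 (adjusted p = 0.87). Feeder fibroblast markers had a median difference of -0.43 with none of 28 called (adjusted p = 0.079, 0.036 with the line as a block, and adjusted p = 0.86 with an estimated correlation).

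The interaction at 24 h called 1377 genes, 959 higher and 418 lower in KO, with 3218 without the 3 libraries and 2413 with the line as a block. Quantile normalization gave 919 higher and 672 lower, so that 57.8% were higher against 69.6%. Among the 1377, 531 had fallen in WT with no call in KO, 351 had risen in WT with no call in KO, 252 had risen in KO with no call in WT, and 65 had fallen in WT and risen in KO. At 8 h limma called 1 gene, Ccsap, with a higher response in KO (0.87 ± 0.15, adjusted p = 0.022), and 769 genes had an unadjusted p under 0.05. The count at 8 h was 74 without the 3 libraries and 52 with the line as a block. Stra8 had an interaction of -3.22 ± 0.84 at 8 h (adjusted p = 0.37, and 1.3e-06 without the 3 libraries).

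At 8 h the list of undifferentiated spermatogonia lay higher in KO, at a median difference of 0.23 with no member called (adjusted p = 3e-06, and adjusted p = 0.064 with an estimated correlation, none adjusted over the list alone). Meiotic prophase lay lower at -0.06 (adjusted p = 6.9e-05, and adjusted p = 0.071 with an estimated correlation, none adjusted over the list alone). Other lists passed the camera test too, among them GDNF and FGF targets at a median of 0.23, RA signalling at 0.21 and G1/S at -0.05. Their adjusted p was 0.00038, 0.0018 and 0.00077, and adjusted p = 0.37, 0.29 and 0.37 with an estimated correlation. Feeder fibroblast markers lay higher at 8 h, at a median of 0.29 with 27 of 28 positive and none called, also adjusted over the list alone. Their adjusted p was 0.021, 0.059 without the 3 libraries, and adjusted p = 0.62 with an estimated correlation. Sertoli markers had a median of 0.22 with none of 14 called (adjusted p = 0.056, 0.014 with the line as a block, and adjusted p = 0.37 with an estimated correlation). At 4 h limma called no interaction, with 1752 genes at an unadjusted p under 0.05. Stra8 had a value of -2.29 ± 0.84 at 4 h (adjusted p = 0.46). Without the 3 libraries it was -2.55, with WT17 as the only WT DMSO library.

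Compared directly at 24 h of RA, KO exceeded WT for Krt73 by a log2 of 3.34 ± 0.44, Kndc1 by 3.02 ± 0.46, Dtx1 by 2.49 ± 0.28 and Gfra1 by 1.22 ± 0.09 (adjusted p = 2.8e-12). It lay below WT for Stra8 (-4.85 ± 0.60), Tgm1 (-1.49 ± 0.16), Perp (-1.33 ± 0.19) and Rgs4 (-1.29 ± 0.17). Tcerg1l (0.60 ± 0.38), Rarb (0.53 ± 0.42) and Cyp26a1 (0.44 ± 0.44) did not pass over all libraries (adjusted p = 0.27, 0.37 and 0.5). Without the 3 libraries these genes passed (adjusted p = 0.0031, 0.02 and 0.039), while Kit (0.05) and Cyp26b1 (-0.16) did not. limma called 4180 genes, 2420 higher and 1760 lower in KO, and 6378 without the 3 libraries. Quantile normalization gave 2101 higher and 2506 lower, so that 45.6% were higher against 57.9%. The balance of directions turned with the scaling.

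Untreated KO and WT cultures had no gene past the threshold in limma, with 479 genes at an unadjusted p under 0.05 and 2 called without the 3 libraries. Gfra1 differed by 0.05 ± 0.09, Kit by 0.07 ± 0.55 and Zbtb16 by -0.04 ± 0.14. Of the camera list tests 9 passed, and none with an estimated correlation. Cholesterol synthesis lay higher in KO, at a median of 0.09 with 22 of 22 positive, and GDNF and FGF targets at 0.08 with 22 of 27. Meiotic prophase lay lower, at -0.06 with 9 of 39 positive. Their adjusted p was 0.00011, 0.0019 and 0.0022, and adjusted p = 0.65, 0.65 and 0.31 with an estimated correlation. Glycolysis and G2/M also lay higher and the piRNA pathway lower. Hox genes had a median difference of 0.14 (adjusted p = 0.00091, and adjusted p = 0.49 with an estimated correlation), with 4 of 19 higher adjusted over the list alone and none over all genes. Feeder fibroblast markers had a median of -0.15 with 3 of 28 positive and none called, also adjusted over the list alone. Their adjusted p was 0.02, 0.075 without the 3 libraries, and adjusted p = 0.73 with an estimated correlation. Endothelial markers had a median of 0.17 with 6 of 7 positive, 1 of them higher adjusted over the list alone (adjusted p = 0.0051, and adjusted p = 0.097 with an estimated correlation). DMSO at 24 h against untreated cultures gave no call in WT (957 genes at an unadjusted p under 0.05) or KO (811) in limma, with 14 in WT and 0 in KO without the 3 libraries and 25 in WT with the line as a block. Stra8 had changes of -0.39 ± 0.60 in WT and 0.18 ± 0.60 in KO.

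Between 4 and 24 h the RA effect grew in WT for Stra8 by a log2 of 3.73 ± 0.84, Foxn4 by 2.83 ± 0.49 and Cyp26b1 by 2.44 ± 0.49. It dropped for Nanos2 (-2.17 ± 0.27), Adcy10 (-2.11 ± 0.29), Zbtb16 (-1.40 ± 0.20) and Gfra1 (-1.16 ± 0.12). In KO it grew for Krt73 by 3.93 ± 0.62, Kndc1 by 3.47 ± 0.66, Kit by 3.13 ± 0.77 and Wnt7b by 2.96 ± 0.56. With the 3 libraries left out the value was 2.44 for Stra8 in WT, where WT17 is then the only DMSO library at 4 h. In KO it was 2.77 for Krt73, 2.28 for Kndc1, 1.9 for Kit and 1.94 for Wnt7b, all past the threshold. limma called 1725 genes in WT, 708 higher and 1017 lower, and 2672 with the line as a block. No count without the 3 libraries is given for WT, for the same reason. In KO limma called 404, 340 higher and 64 lower, with 240 without the 3 libraries and 1076 with the line as a block.

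The authors' deposited table lists, at the same threshold, 523, 2273 and 6360 genes for RA in WT at 4, 8 and 24 h and 527, 1222 and 3301 in KO. Over 7915 genes, which are not independent replicates, the fold changes at 4 h in the authors' deposited table correlated with those of all libraries at r 0.561 in WT and 0.723 in KO. Without the library labelled WT25 the r in WT was 0.976, and without KO20 the r in KO was 0.967. Of the genes called here, 279, 832 and 3923 in WT and 71, 521 and 1433 in KO were also past the threshold there with the same sign, and none with the opposite sign. The authors' deposited table of interactions lists 0, 113 and 3498 genes, with 10 libraries at 4 h and 12 at 8 and 24 h per its headers. Its values have the sign of WT minus KO, with 1329 of the 1377 genes called here past the threshold there with the opposite sign.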

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

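The tests on the 3 DMSO libraries at 4 h and the fits without them were chosen after their values were seen, while the counts over other splits of the samples were planned. Differences between 2 effects of RA, between the genotypes or between times, are given for genes that passed a limma test of that difference.

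Between the genotypes, 1 gene passed at 8 h (Ccsap, 0.87) and 1377 at 24 h. The RA effect at 24 h was higher in KO, in log2, for Krt73 (3.19), Kndc1 (3.08), Dnah17 (2.64), Slc5a4a (2.62), Dtx1 (2.47), Gdap1l1 (2.44), the antiviral enzyme Oas3 (2.28), Tm4sf5 (2.19), Gpr179 (2.18) and Slc10a4 (2.15). It was lower in KO for Stra8 (-3.75), Ikzf1 (-1.41), Perp (-1.36), Grb14 (-1.31), Tgm1 (-1.28), Fam167a (-1.26), Dpysl4 (-1.19), Ppp4r4 (-1.15), Map2 (-1.14) and the dynein gene Dnah10 (-1.13).

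Among spermatogonial genes the difference at 24 h was positive for Nanos3 (2.01), Nanos2 (1.71), Plvap (1.5), Utf1 (1.39), Dmrtb1 (1.20), Gfra1 (1.11) and Zbtb16 (0.87). Among GDNF and FGF targets it was positive for Egr4 (1.72), Nefm (1.46), Mycn (1.38) and Egr2 (1.26). RA and Hox genes with a positive difference were Bco1 (2.12), Hoxb1 (1.19) and Dhrs3 (0.83). Meiotic genes with a negative difference were Ugt8a (-0.49), Dmc1 (-0.38) and Smc1b (-0.38), and the piRNA pathway genes Piwil4 (0.41) and Tdrd5 (0.40) had positive ones. Cell cycle, apoptosis and chromatin genes were Chaf1b (0.97), Ccnd2 (0.73), Ccne2 (-0.61), Nusap1 (-0.52), Sesn1 (0.71), Trp73 (0.68), Scmh1 (0.49) and the immediate early gene Maff (1.02). Metabolic genes were Dhcr7 (0.58), Pkm (0.56), Srebf2 (0.47), mt-Nd2 (0.31) and Uqcrc2 (-0.21). Markers of other cells were the endothelial genes Pecam1 (1.97) and Vwf (1.19) and the macrophage gene Mrc1 (1.24). Under quantile normalization the calls of Trp73, mt-Nd2 and Mrc1 were lost (adjusted p = 0.063, 0.87 and 0.054).

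Between times, the RA effect at 24 h differed from that at 4 h for 1725 genes in WT and 404 in KO. In WT it was higher at 24 h for Stra8 (3.73), Foxn4 (2.83), Cyp26b1 (2.44), Fam167a (2.14) and Ogn (1.96). It was lower for Nanos2 (-2.17), Adcy10 (-2.11), Ccdc141 (-2.07), Tmem178b (-2), Mypn (-1.99), Zbtb16 (-1.40) and Gfra1 (-1.16). In KO it was higher for Krt73 (3.93), Kndc1 (3.47), Tm4sf5 (3.40), Kit (3.13), Wnt7b (2.96), Cyp26b1 (2.78), Rarb (2.38) and Tcerg1l (1.95). It was lower for Tmem178b (-1.61), Cd3g (-1.29), Fign (-1.15), Adgrl3 (-1.09) and Hmgn5 (-1.09). Without the 3 libraries the calls of Fign and Hmgn5 in KO were lost (adjusted p = 0.14 and 0.09). Without them the WT value was 2.44 for Stra8, 1.98 for Ogn and -1.34 for Tmem178b, with WT17 as the only DMSO library at 4 h. In KO it was 2.77 for Krt73, 2.28 for Kndc1, 2.25 for Tm4sf5, 1.9 for Kit, 1.94 for Wnt7b, 2.05 for Cyp26b1, 1.36 for Rarb and 1.02 for Tcerg1l, each still past the threshold. Under quantile normalization the call of Tcerg1l in KO was lost, at 1.88 (adjusted p = 0.054).

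Splits were made of 6 libraries, for the interaction of the 6 culture lines, and for the contrast of times of the 6 pairs of RA and DMSO libraries of a line. The 6 units can be split in 10 ways, so that no share under 0.05 can be reached. The real split was 1 of 10 with as many genes for RA in WT at 8 h (834) and 24 h (3949), in KO at 8 h (523) and 24 h (1440), and for the interaction at 8 h (1) and 24 h (1377). It was also 1 of 10 for the contrast of times in WT (1725) and KO (404) and for KO against WT at 24 h of RA (4180), with 0 genes in the highest other split of each. Other splits put libraries that differ by treatment, time or genotype into 1 group, so a real effect widens the spread there. Few calls in them are thus likely in advance and lend no support. For KO against WT untreated and DMSO at 24 h against untreated, all 10 splits gave 0. For the interaction at 4 h, with 0 genes, 10 gave as many and the highest other gave 1. In WT at 4 h, 2 of 10 splits gave as many as the real 489 genes, the higher with 1175. It set the DMSO libraries of WT17 and WT23 and the RA library of WT23 against the rest, which points to a structure of the samples. The splits that part all pairs of a line gave at most 1. In KO at 4 h, 3 of 10 splits gave as many as the real 75, the highest with 286 (the DMSO libraries of KO12 and KO21 with the RA library of KO21), and those that part all pairs gave at most 53.

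The library labelled KO20 DMSO 4 h lay beside KO at 24 h of RA, and a candidate explanation is a wrong label, with RNA of line KO20 at 24 h of RA in its place, since the SD of its differences from KO20 at 24 h of RA was 0.0403, against 0.102 for the lowest of 860 other pairs of libraries. Whether the columns hold 1 library deposited under 2 labels stays open, since counting noise at the mean scaled count of these genes would give an SD of 0.0549 but the depth of these libraries is unknown, so the 42 columns may not be distinct libraries. Partial admixture of such RNA is argued against by a median of 100% of the change at 24 h of RA in KO, within the 95.9 to 106% of the libraries of that group. A swap within the series would need a library of that group without the RA change, and the lowest had 95.9%. No biological explanation was tested.

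The library labelled WT23 DMSO 4 h had raised RA-induced genes, with a median of 15.4% of the WT change at 24 h over the 131 genes that rose, against at most 4.24% in other WT libraries without RA. Admixture of RNA from a KO culture at 24 h of RA is argued against by genes that rose in KO and not in WT, at -1.23% against up to 1.99% in other WT libraries without RA. A wrong label, with RNA of WT at 4 h of RA, is argued against by the same genes, which stood at 14.4 to 17.1% in the WT libraries at 4 h of RA. Admixture from WT at 24 h of RA and RA in the culture at an unknown dose or time cannot be told apart, since the genes that fell stood at 14.9% against up to 16% in other libraries, and genes that change late at 9.45% against up to 10%. No biological explanation was tested.

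The library labelled WT25 DMSO 4 h stood apart from WT17 and WT23 over many genes. A candidate explanation for part of this is a bias by transcript length, since the deviation correlated over genes with the length of the longest transcript at a rho of -0.622, against -0.214 to 0.199 in 39 other libraries. Length as the whole cause is argued against by an SD of 0.414 after the length trend was removed (0.522 before), above the 0.248 of any library outside the DMSO groups at 4 h. GC content is argued against as well (rho 0.179, within -0.457 to 0.342). A larger form of the change over 4 h of culture was compared only with that change in KO12 and KO21 (r 0.0556 over genes). No WT line entered that comparison, so it cannot decide for WT25. No biological explanation was tested, and what else sets this library apart stays open.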

How the results depend on the processing

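The fits without 2 or 3 of the DMSO libraries at 4 h were chosen after the data were seen, and the other settings were planned. The cause of the changes with a setting was not tested, except that fits on fewer libraries estimate the spread from fewer values and fits without the libraries in doubt have less spread. Of 688 results for named genes, tried in 9448 alternative values, 8697 stayed on the same side of the threshold, 654 were no longer past it, 97 passed it newly and 0 of those past it in either fit turned direction. Of 4595 values past it in neither fit, 338 changed sign. The 2-fold limit was not applied to the results for named genes. In all the other settings the call held for 59 of 80 named genes in WT at 24 h, 23 of 51 at 8 h and 1 of 34 at 4 h. In KO it held for 23 of 52, 15 of 27 and 0 of 12. It held for 35 of 60 interactions at 24 h and 0 of 1 at 8 h, for 8 of 12 and 0 of 13 contrasts of times in WT and KO, and for 13 of 13 in KO against WT at 24 h of RA. Depth is unknown, so it cannot be said which low genes were limited by counting.

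With a 2-fold limit, the RA comparisons called 42, 88 and 388 genes in WT at 4, 8 and 24 h and 13, 141 and 265 in KO. The interaction called 0 at 8 h and 370 at 24 h, the contrast of times 316 in WT and 204 in KO, and KO against WT at 24 h of RA 437. Genes that rose in both genotypes numbered 11, 53 and 55 at 4, 8 and 24 h, and those that fell in both 0, 1 and 6.

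With the culture line as a replicate block, WT at 4 and 8 h had 1458 and 1501 genes and KO 186, 885 and 2366 at 4, 8 and 24 h. The interaction had 52 at 8 h and 2413 at 24 h, the contrast of times 2672 in WT and 1076 in KO, and DMSO in WT 25. Shared rises were 116 at 4 h and 535 at 24 h, shared falls 10, 121 and 419 at 4, 8 and 24 h. Genes lower in WT and higher in KO at 24 h went from 65 to 177 (161 without the 3 libraries), and 3 gene lists passed in KO at 8 h. The block moved no other count of genes by over 1.5 times, and 7 of the 688 results for named genes passed newly with it and none was lost. With only the groups compared, WT at 4 h had 23 genes, KO 1 at 4 h and 2883 at 24 h. The interaction had 13 at 8 h and 3142 at 24 h, the contrast of times 629 in WT and 0 in KO, and DMSO 2 in WT and 1 in KO.

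Without the 3 libraries in doubt, WT had 230, 1958 and 6054 genes at 4, 8 and 24 h, and KO 448, 1068 and 3023. The interaction had 74 and 3218 at 8 and 24 h, and the contrast of times in KO 240. KO against WT had 2 untreated and 6378 at 24 h of RA, and DMSO in WT 14. Shared rises were 172, 426 and 691 and shared falls 12, 154 and 691. Gene lists past the threshold were 3 in KO at 4 h and 3 in KO at 8 h. Without the 2 libraries that the authors' column names remark on, WT had 1938 and 6076 at 8 and 24 h, and KO 434, 1078 and 3005. The interaction had 74 and 3238 at 8 and 24 h, the contrast of times 3080 in WT and 240 in KO, KO against WT 1 untreated and 6387 at 24 h of RA, and DMSO in WT 12. Shared rises were then 249, 424 and 689, shared falls 11, 153 and 684, and gene lists 0 in WT at 4 h, 3 in KO at 4 h and 3 in KO at 8 h. Without the library labelled KO20 DMSO 4 h alone, WT had 829 and KO 322 genes at 4 h, without WT25 alone 184 and 142, and without WT23 alone WT had 4297.

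With no filter on low values, the interaction at 8 h had 4 genes, KO against WT untreated 6, and DMSO 12 in WT and 1 in KO, and limma without trend and robust options gave 4 for DMSO in WT. With an estimated correlation, the gene lists past the threshold went from 1, 8 and 10 to 0, 0 and 1 in WT at 4, 8 and 24 h, from 6, 5 and 7 to 0, 0 and 0 in KO. They went from 4, 13 and 7 to 0, 0 and 1 for the interaction and from 9 to 0 for KO against WT untreated. The lists that held were undifferentiated spermatogonia in WT and in the interaction at 24 h.

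Leaving out each line in turn gave 63 to 1912 genes in WT at 4 h (63 without WT25 and 1912 without WT17), 256 to 955 at 8 h and 2346 to 3894 at 24 h. The ranges in KO were 11 to 189, 198 to 578 and 605 to 1918, and for the interaction 0 to 0, 0 to 5 and 636 to 1705. They were for the contrast of times 790 to 1789 in WT and 55 to 415 in KO, for KO against WT 0 to 1 untreated and 2693 to 4771 at 24 h of RA, and for DMSO 0 to 4 in WT and 0 to 0 in KO. Quantile normalization left the median of all genes between -0.043 and 0.025 and moved the share of higher calls by over 10 points in the interaction at 24 h (69.6% to 57.8%) and in KO against WT at 24 h of RA (57.9% to 45.6%). Other pseudocounts did not apply to values already on a log scale, the 2 samples of WT17 at 24 h of RA could not be tried apart with 1 column, and the gene list test with the line as a block was not run for KO against WT untreated, since each line belongs to 1 genotype.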

Other observations

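The test of signs at 8 h and the choice of the 65 genes described first were made after their values were seen. At 24 h of RA, 65 genes fell in WT and rose in KO with a difference past the limma test. Genes that fell in WT and rose in KO numbered 161 without the 3 DMSO libraries in doubt and 177 with the culture line as a block. The test of the difference was not applied to the counts of 161 and 177. Mypn, a sarcomere protein gene, fell by 1.46 ± 0.12 in WT (SE, n = 3 lines) and rose by 0.52 ± 0.12 in KO, and Lpar3, a receptor for lysophosphatidic acid, fell by 1.30 ± 0.11 and rose by 0.57 ± 0.11. Rhobtb1 fell by 1.05 ± 0.21 and rose by 1.02 ± 0.21, the Hedgehog receptor Ptch1 fell by 1.08 ± 0.20 and rose by 0.69 ± 0.20, the integrin Itga9 fell by 1.07 ± 0.25 and rose by 0.83 ± 0.25, and Cd93 fell by 0.97 ± 0.12 and rose by 0.78 ± 0.12.

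Some markers of other cell types were part of the same difference. Pecam1, an adhesion molecule of endothelium that is also found in early germ cells, fell by 0.67 ± 0.24 in WT and rose by 1.30 ± 0.24 in KO. Mrc1, a mannose receptor of macrophages, fell by 1.85 ± 0.26 in WT with a change of -0.61 ± 0.26 in KO (adjusted p = 0.17), and its interaction was 1.24 ± 0.37 (adjusted p = 0.031, but 0.054 under quantile normalization). As lists, neither passed the camera test of the interaction at 24 h. Endothelial markers had 2 of 7 members higher (adjusted p = 0.087, but 0.035 with the line as a block and 0.21 without the 3 libraries). Macrophage markers had 1 of 5 higher (adjusted p = 0.24).

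Only 1 gene passed the interaction at 8 h, and the genes of 24 h were compared with their own signs at 8 h. Of the 1377 genes called at 24 h, 95.4% had an interaction of the same sign at 8 h, which is consistent with a difference that was already under way at 8 h, as a hypothesis. A constant difference between culture lines cancels between RA and DMSO. A response to RA that differs between lines may also give such a share, since the same lines were sampled at both times. The 9 other splits of the 6 lines, with as many top genes each, gave 67.2 to 79.6%. The real split lay above every other. As 10 splits can give no share under 0.05, the splits alone do not decide between line and genotype.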
